A study of Mus musculus with 33 samples.

How the data were processed

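RNA was sequenced from tibialis anterior (TA), cultured myotubes and choroid plexus of mice with an expanded CTG repeat in Dmpk and of wild-type mice. Read quality was checked with FastQC and reads were aligned with STAR to mm10, per the submitters' processing notes, which give no versions. The program that called splicing events is not given in the sources used here. The 20 deposited tables hold 5 event types (skipped exon, alternative 5′ splice site, alternative 3′ splice site, mutually exclusive exons and retained intron) in 4 comparisons. Per the file headers, the authors kept events with an average of 5 reads or more, an FDR of 0.05 or less and an absolute inclusion difference of 0.1 or more. Each event has a p-value and an FDR computed by the authors, which were taken as deposited. Inclusion is given by the authors as a fraction from 0 to 1 for each library, and their difference column is wild type minus expansion.

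Fractions were turned into percentages, and each change was computed as expansion minus wild type, from the group means of the library values. The recomputed changes lay within 0.05 percentage points of the deposited differences. Groups were taken from the labels: 7 groups with 21 labelled libraries were used, and 4 groups with 12 libraries are in no splicing table and were not analysed here. Replicates are separate mice, per the labels. For 480/480 choroid plexus the tables hold 2 values for 3 labelled libraries (n = 2), and which library was left out is not stated. The lists of library values carry no replicate number, so libraries are named by their place in the list. Counts were not used here, so the depth is unknown beyond the authors' minimum of 5 reads, and no counting interval is given for an event. All 376 gene IDs matched a current symbol, and 10 genes (12 events) had their symbol replaced. Which of a pair of mutually exclusive exons a value describes was checked against skipped-exon events at the same exons: on the plus strand the first exon moved with the value in 15 of 15 cases, and on the minus strand the second did in 4 of 4.

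The comparisons, tests, 9 gene lists and the rule for named genes were chosen before the data were examined. Named genes were, in each comparison, the 12 largest skipped-exon changes with 1 per gene, the 2 largest of each other event type, up to 10 members of the list of known muscle targets (brain targets for choroid plexus) and up to 4 of each other list. Exons in 3 comparisons or more were to be named too, but there were none. For 2 genes that meet the rule, results are not reported here. Dmpk is named as the edited gene, and genes named beyond this rule were chosen after their values were seen. Direction was tested with exact two-sided binomial tests, sizes and exon lengths with two-sided permutation tests of medians (100000 resamples, smallest p 1e-05), event types with a chi-square permutation test, and lists and reading frame between tables with Fisher's exact test. Each family was adjusted by the Benjamini-Hochberg method. Lists were compared between tables only, since the tables hold selected events and no background of tested genes. Exons were matched between tables by gene, start and end. Coding, UTR and cassette exons came from GENCODE mouse M21. Wilson intervals are at 95%. The agreement of the myotube tables was set beside 1000 simulations of unchanged groups against the shared controls.

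The alternatives fixed in advance were the authors' FDR at 0.01 or less, a change of 20 points or more, 1 event per gene, other rules for a shared event and leaving out each library. Added after the data were seen were the removal of events with a group at 0% or 100% in every library, an SD under 10 points in both groups, the same flanking exons and wholly coding exons. A search for binding motifs around exons was planned and not run, because no genome sequence was used here. The calculation was tested on simulated data for the 184 skipped exons of 480/480 myotubes, with a spread of 5 points where a change was put in. Changes of 20 and 40 points kept their direction in 100% of exons, with mean errors of -0.261 and 0.218 points. The smallest exact p was reached by 99.5% and 100% of them. With no change, simulated with a wider spread and without the exons' own values, 12.5% reached it. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.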

Results

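RNA was sequenced from 3 tissues of mice that carry an expanded CTG repeat in Dmpk, the gene whose repeat in the 3′ untranslated region (UTR) is expanded in myotonic dystrophy. The edited allele named 480 holds 480 repeats, and the libraries used here are from wild-type, +/480 (1 expanded allele) and 480/480 (2 expanded alleles) mice. The tissues were tibialis anterior (TA), a fast muscle of the lower leg, myotubes, which are multinucleate muscle cells differentiated in culture, and choroid plexus, the brain tissue that secretes cerebrospinal fluid. The labels list 33 libraries in 11 groups of 3. The splicing tables compare 7 of these groups, all on the FVB strain, and the other 4 groups with 12 libraries, +/480 TA, +/480 choroid plexus, and 170/170 and wild-type myotubes of the BL6 strain, were not analysed here. By the mouse given in the labels, the same 3 mice of a genotype were the source of its TA, myotube and choroid plexus libraries, so replicates are separate mice while the tissues are not independent of each other.

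The tables hold 549 splicing events: 81 in 480/480 TA, 243 in 480/480 myotubes, 110 in +/480 myotubes and 115 in 480/480 choroid plexus, each against wild type of the same tissue. Every event had passed the authors' selection (at least 5 reads on average, FDR at most 0.05 and an inclusion change of at least 10 percentage points), and "rose" and "fell" are used here for events that passed it. Inclusion is the percentage of transcripts that hold an exon, the longer form of an exon or a retained intron, given as mean ± SD over 3 libraries per group (n = 3), and over 2 libraries (n = 2) in 480/480 choroid plexus. The choroid plexus tables hold values for 2 of its 3 labelled 480/480 libraries and do not say which was left out. Counts per event were not used here, so the depth behind each value is unknown. An exact two-sided permutation test of 3 libraries against 3, or of 3 against 2, cannot go below p = 0.10, so no p-value per event was added to the authors' own. Coordinates are on mm10.

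Dmpk itself, the edited gene, had different events in TA and in 480/480 myotubes. Reads were aligned to mm10, and whether the edited sequence affects the values near the 3′ end of the gene was not tested. In TA, a coding exon of Dmpk (chromosome 7, 19086893 to 19087041) fell from 96.8% ± 0.379 to 78.6% ± 6.99, and the authors' deposited table lists its FDR as 0. Near the 3′ end of the gene, retention of a 3′ intron (chromosome 7, 19092037 to 19092207) rose from 7.50% ± 4.18 to 23.4% ± 8.49. The longer form at a 5′ splice site there rose from 87.7% ± 2.10 to 100% ± 0. The longer form of an exon with 2 possible 3′ splice sites (chromosome 7, 19092418 to 19092632) rose in TA from 72.4% ± 4.68 to 100% ± 0. In 480/480 myotubes the longer form of that same exon fell instead, from 51.7% ± 1.31 to 27.1% ± 1.65. The TA and myotube events at this exon have different neighbouring exons, so they are not the same event. No Dmpk event is in the +/480 myotube or choroid plexus tables.

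In 480/480 myotubes many events lay in muscle genes, and 22 of the 69 genes listed beforehand as splice targets in myotonic dystrophy muscle had at least 1 event. Tnnt2, which encodes cardiac troponin T of the thin filament, included a 30-base coding exon (chromosome 1, 135843785 to 135843814) at 23.9% ± 1.56 in wild type and 65% ± 8.82 in 480/480 (SD, n = 3 each). Tnnt3, the fast skeletal troponin T, rose at a 39-base coding exon (chromosome 7, 142507750 to 142507788) from 71.8% ± 3.48 to 97.6% ± 0.115. Cacna1s, the voltage-sensing calcium channel of skeletal muscle, fell at a coding exon (chromosome 1, 136104570 to 136104626) from 37.8% ± 5.14 to 16.1% ± 2.72. Mbnl1, a splicing regulator known to bind expanded CUG repeat RNA, rose at a 54-base coding exon (chromosome 3, 60614683 to 60614736) from 23.5% ± 7.25 to 46.4% ± 11.6. The authors' FDR for it was 0.0496, close to their threshold of 0.05.

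The 22 target genes carried 60 events, of which 29 rose and 31 fell. Counts by list or gene pool all event types, and an exon can be counted under several, as with Clasp1. For mutually exclusive exons, rising or falling refers only to the exon that the value follows, so these counts give no net direction of inclusion. Slain2, a microtubule-binding protein, fell from 76.3% ± 1.36 to 50.7% ± 6.26, and Vps39, a tethering factor of endosomes and lysosomes, fell from 40.2% ± 5.30 to 11.4% ± 6.42. Rapgef1, an exchange factor for Rap1, fell from 80.9% ± 6.67 to 48.3% ± 9.51, while the Notch ligand Jag2 rose from 34.4% ± 2.45 to 60.7% ± 8.16. Inclusion of 1 of 2 mutually exclusive exons of Pdlim3, a Z-disc protein, rose from 25.3% ± 2.35 to 53.6% ± 9.35. Spp1, which encodes osteopontin, averaged 79.2% ± 35.4 in wild type and 38.3% ± 2.45 in 480/480 with overlapping libraries. Of 72 sarcomere and Z-disc genes, 15 had 53 events, 26 of them higher and 27 lower. Ttn, the giant spring protein titin, had 6 events that all fell, and its largest was 86.4% ± 23.6 in wild type against 45% ± 13.4 with overlapping libraries. Neb, the thin-filament protein nebulin, had 8 events (3 higher and 5 lower), and Tnnt3 had 8 (5 higher and 3 lower).

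Outside the sarcomere, 4 of 59 calcium-handling and excitability genes had 5 events in 480/480 myotubes, 1 higher and 4 lower. Besides Cacna1s these included Cacna2d1, an auxiliary calcium channel subunit, which fell from 50.5% ± 12.5 to 15.2% ± 2.92, and the kinase Camk2g, which fell from 95.3% ± 4.36 to 78.4% ± 7.20. Of 107 cytoskeleton and adhesion genes, 19 had 28 events, 11 higher and 17 lower. The microtubule plus-end protein Clasp1 fell from 78.3% ± 11 to 35.9% ± 9.97, and the membrane protein Palm fell from 39% ± 4.45 to 10.6% ± 3.46. Dnm1l, the dynamin of mitochondrial fission, rose from 36.8% ± 9.12 to 66.7% ± 12.3. Dnm2, a dynamin of membrane scission, fell at one 139-base exon from 53.4% ± 7.07 to 24% ± 5.07 and rose at a neighbouring 139-base exon from 23.2% ± 2.49 to 48.4% ± 7.61. Of 42 targets known from brain, 7 had 10 events (4 higher and 6 lower), among them Ndrg4 from 69.7% ± 10.02 to 44.2% ± 11.4 and Ppp1r12a, the targeting subunit of myosin phosphatase, from 75.7% ± 7.21 to 91% ± 3.95. Mbnl1 was the only 1 of 103 RNA-binding proteins with an event. Of 69 choroid plexus epithelium genes, 2 had 3 events that all fell, Calml4 from 96.9% ± 5.31 to 77.3% ± 10.6 and the junction protein Tjp1 from 19.4% ± 0.907 to 8.73% ± 2.14. None of the 46 markers of other choroid plexus cells and none of the 30 markers of other muscle cells had an event.

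The largest skipped-exon changes in 480/480 myotubes were mostly in genes outside these lists. Rilpl1, a Rab-interacting protein, fell at a 24-base coding exon (chromosome 5, 124495899 to 124495922) from 79.3% ± 4.68 to 29.2% ± 3.27, and the authors' deposited table lists its FDR as 0. Phospholipase D gene Pld1 fell from 95.2% ± 8.31 to 46.6% ± 4.16, the growth factor receptor Fgfr3 rose from 34% ± 10.1 to 82.9% ± 15.8, and the autophagy enzyme Atg7 fell at a 5′ UTR exon from 89.1% ± 18.9 to 34.3% ± 17.5. The deubiquitinase Josd2 fell at a 5′ UTR exon from 84.3% ± 27.1 to 21.1% ± 10.4, the largest skipped-exon change in this table. Ggta1 fell from 92.9% ± 12.2 to 42% ± 18.2, Rusc1 from 81.2% ± 32.6 to 28.9% ± 13.5, and Csnk1g1 rose from 33% ± 15.1 to 85.8% ± 24.7. Wild-type libraries were widely spread at Sptbn5, Trip4 and Zfp939, where wild type averaged 44.4% ± 29.1, 45% ± 47.7 and 55.6% ± 44.1 and every 480/480 library was at 100%. At the other event types, the longer exon form of Hoxa11os was listed at 0% in wild type and 88.3% ± 20.2 in 480/480, Synj1 fell from 100% ± 0 to 52.4% ± 5.83, Fbxl12 from 88.2% ± 20.5 to 50.2% ± 4.04 and Strada from 100% ± 0 to 53.6% ± 39.5. Retention of an intron of A230050P20Rik fell from 100% ± 0 to 16.7% ± 8.83. The groups did not overlap at 218 of the 243 events (89.7%, where chance gives 10% for 3 libraries against 3 before any selection).

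**Figure D1:**
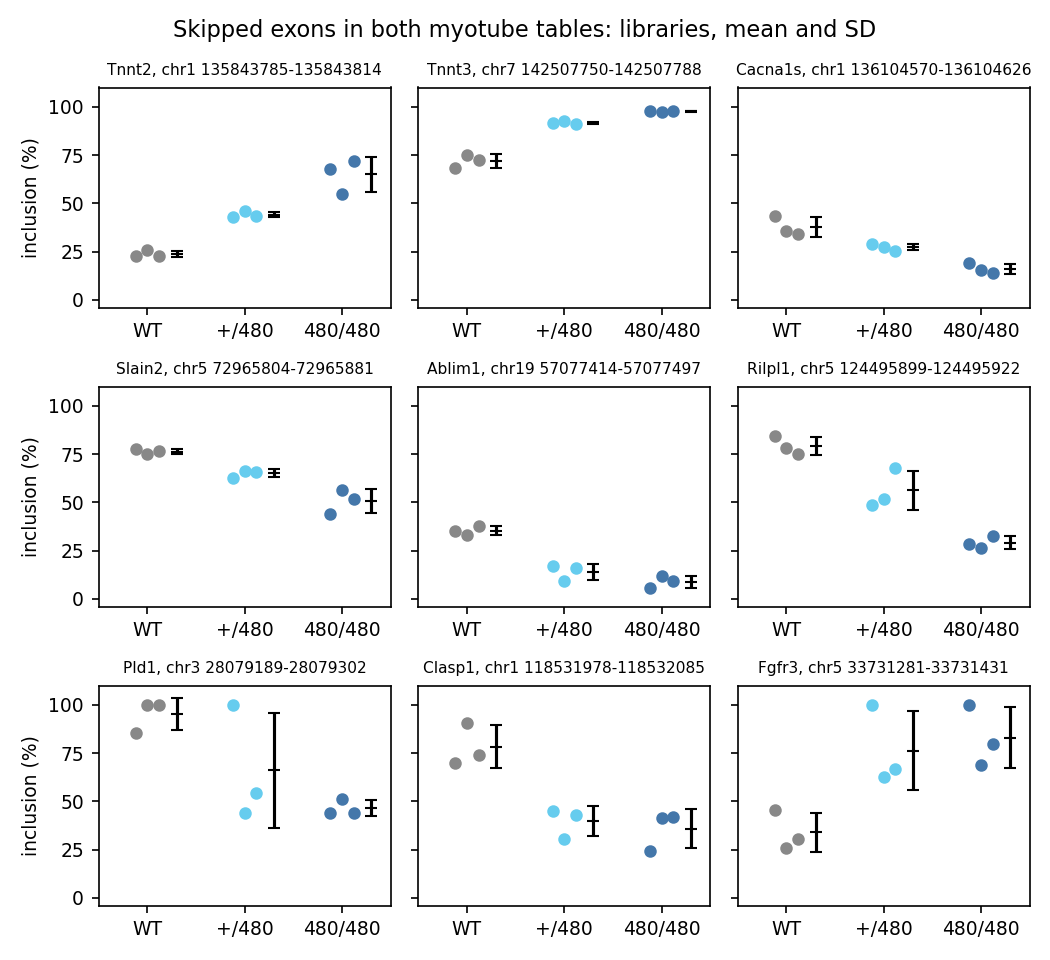
Inclusion (%, vertical axis) of 9 skipped exons found in both myotube tables, in wild type (grey), +/480 (light blue) and 480/480 (dark blue); points are libraries, and the bars beside them are mean and SD (n = 3). Mean inclusion of Tnnt2 was 23.9%, 44.2% and 65% in the 3 genotypes, and that of Cacna1s 37.8%, 27.3% and 16.1%.

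The +/480 myotubes, with 1 expanded allele, had events at several of the same muscle exons. The same Tnnt2 exon rose from 23.9% ± 1.56 to 44.2% ± 1.49 (SD, n = 3 each), the Tnnt3 exon rose from 71.8% ± 3.48 to 91.8% ± 0.557, and the Cacna1s exon fell from 37.8% ± 5.14 to 27.3% ± 1.60. Ablim1, an actin-binding LIM protein, fell from 35.4% ± 2.55 to 13.9% ± 4.13, and Clasp1 fell from 78.3% ± 11 to 39.6% ± 7.79. Ryr1, the calcium release channel of muscle, rose from 9.70% ± 4.09 to 20.4% ± 3.38 at a 21-base coding exon (chromosome 7, 29117208 to 29117228). Of the 69 muscle targets 8 had 18 events, 11 higher and 7 lower. Slain2 fell from 76.3% ± 1.36 to 65% ± 2.04, Pdlim3 rose from 25.3% ± 2.35 to 38.8% ± 2.35, and 2 Ttn exons rose, the larger averaging 65% ± 14.5 in wild type and 91.3% ± 15.1 in +/480 with overlapping libraries.

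Among the other lists in +/480 myotubes, 6 of 72 sarcomere genes had 16 events (10 higher and 6 lower), 2 of 59 calcium-handling genes had 2 (1 higher and 1 lower), and 7 of 107 cytoskeleton genes had 10 (3 higher and 7 lower). The polarity protein Scrib rose from 70.8% ± 2.60 to 92.9% ± 3.46, and Abi2 intron retention averaged 100% ± 0 in wild type and 49.5% ± 43.9 in +/480, with overlapping libraries. No brain target or RNA-binding protein of the lists had an event. Of 69 choroid plexus epithelium genes, 2 had 2 events, Folr1 from 78% ± 9.60 to 100% ± 0 and Tjp1 from 19.4% ± 0.907 to 8.17% ± 2.06. No marker of other choroid plexus cells had an event, and 1 of 30 markers of other muscle cells did, Fn1 (fibronectin), with 82.5% ± 3.55 in wild type and 94.3% ± 7.35 in +/480. The largest skipped-exon changes were in Rian, an imprinted non-coding RNA, from 23.3% ± 20.2 to 94.6% ± 9.30, the guidance receptor Robo2 from 45.5% ± 21 to 100% ± 0, Kazald1 from 29.4% ± 6.29 to 82.7% ± 29.96 and the transcription factor Runx2 from 33% ± 9.97 to 86.1% ± 24.1, which all rose. Fam151b fell from 100% ± 0 to 50.8% ± 12.9, Gtf2i from 100% ± 0 to 54.6% ± 10.5 and Sema6c from 89.1% ± 18.9 to 41.7% ± 5.44. Huwe1, a ubiquitin ligase, rose from 45.9% ± 18.5 to 93.3% ± 11.6, Cdc42bpa from 43.5% ± 11.3 to 90.7% ± 16.2 and Rxfp1 from 54.6% ± 14.9 to 97% ± 5.25. The longer 5′ splice-site form of Tbp, the TATA-binding protein, rose from 32.6% ± 15.9 to 94% ± 10.4, and retention of an intron of the replication kinase Cdc7 rose from 16.8% ± 15.2 to 100% ± 0 while that of Cetn4 fell from 100% ± 0 to 16% ± 9.15. The groups did not overlap at 89 of 110 events (80.9%, chance 10% before any selection).

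Comparing 1 with 2 expanded alleles, 32 skipped exons were in both myotube tables and 31 of them changed in the same direction. Tnnt2 rose by 20.3 percentage points in +/480 and by 41.1 in 480/480, Rilpl1 fell by 23.1 and 50.1, Cacna1s fell by 10.5 and 21.7, and Slain2 fell by 11.3 and 25.6. Clasp1 (fell by 38.7 and 42.4) and Ablim1 (fell by 21.5 and 26.5) were closer. Sema6c, Scrib, Tjp1, Aak1, Cdpf1 and Sept4 had the larger change in +/480, as did Cdc42bpa, whose events have different flanking exons in the tables. An exon of Ttn (chromosome 2, 76838812 to 76838895) was the 1 with opposite signs, rising by 14.3 points in +/480 and falling in 480/480 (fell by 27.0), but with different flanking exons in the tables. The change was larger in 480/480 for 25 of the 32 exons (exact two-sided binomial p = 0.00210). The tests of this comparison treat exons measured in the same libraries as independent, among them exons of the same gene in Sdr39u1 and in Dnm2. Their p-values describe the listed exons and not mice. The mean difference in size was 5.46 points (SD 10.5; sign-flip permutation p = 0.0052, two-sided). The 25 include Ttn, with its opposite signs, and Pdp1, and the events compared for both have different flanking exons, like those of Cdc42bpa. A smaller 480/480 event of Pdp1 has the same flanking exons as its +/480 event, and in that pair the change was larger in +/480. That pair is counted in the next comparison. Over the 31 pairs of events with the same exon and flanking exons (30 exons, with 2 pairs at the Tnnt2 exon) the share was 77.4% (exact two-sided binomial p = 0.00333) and the mean difference 6.72 points (sign-flip permutation p = 0.0001). Median change was 26.0 points in 480/480 and 20.5 in +/480, and the median ratio of +/480 to 480/480 was 0.800. Another 146 exons were in the 480/480 table only and 36 in the +/480 table only, which was not tested as a difference. Without the value listed first for +/480 the mean difference was 4.10 points (sign-flip permutation p = 0.0833). Without the second the share larger in 480/480 was 65.6% (exact binomial p = 0.110), and without the first for 480/480 it was 68.8% (p = 0.0501).

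Both myotube comparisons use the same wild-type libraries, which alone makes changes look alike. Across the 32 shared exons, which are not independent replicates, Pearson's r was 0.902 and Spearman's rho 0.878 (permutation p = 1e-05 for each, the smallest possible with 100000 resamples). The share in the same direction, 96.9%, differed from 50% (exact two-sided binomial p = 1.54e-08, Benjamini-Hochberg adjusted 7.68e-08 over the pairs of tables that share exons). With shared controls, 50% is not the share that unchanged groups would give. None of these p-values allows for the shared controls, so they are no evidence of agreement beyond them. The observed share is better set beside the 90.4% of the simulations that follow. In 1000 simulations with unchanged expansion groups against these controls, 90.4% of the exons past 10 points in both tables had the same direction. Over the 31 pairs of events with the same flanking exons, the mean simulated correlation was 0.494, against 0.951 observed. The covariance was 26.3 in the simulations and 697 observed, a difference of 671. The observed pairs had been selected for passing 10 points in both tables and the simulated ones had not, which can raise both observed values. Neither gap therefore measures agreement beyond the shared controls. The 3 wild-type libraries are too few to split, so how much of the agreement comes from the shared controls is not known.

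**Figure D2:**
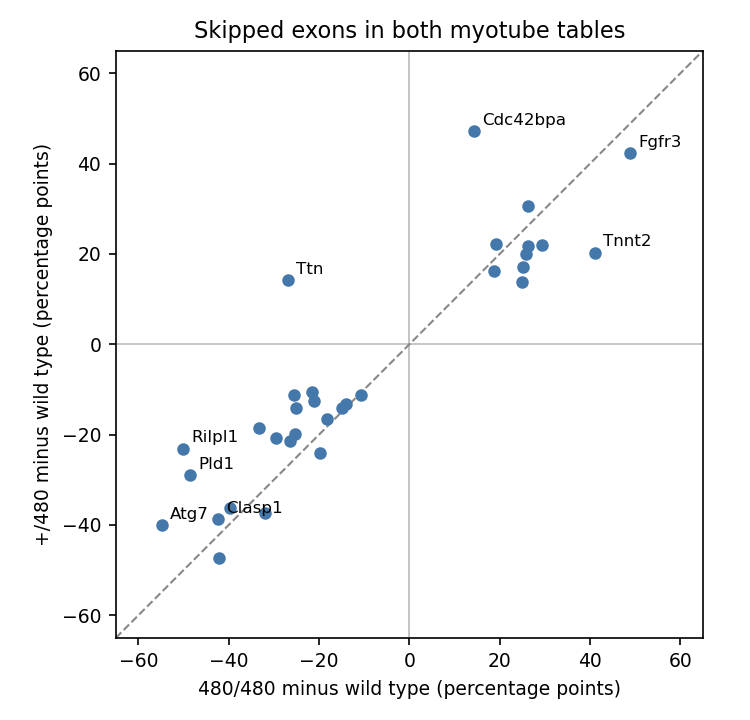
Change in inclusion against wild type (percentage points) of the 32 skipped exons in both myotube tables, 480/480 on the horizontal axis and +/480 on the vertical axis, each point an exon; the dashed line marks equal changes. Of the 32 exons 25 had the larger change in 480/480, and the Ttn exon has opposite signs.

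In TA, the adult muscle of the same mice, none of the 69 muscle splice targets had an event. The microtubule-severing gene Fign rose at a partly coding exon (chromosome 2, 64096895 to 64097064) from 45.5% ± 12.9 to 100% ± 0 (SD, n = 3 each), and Josd2 fell at its 5′ UTR exon (chromosome 7, 44468360 to 44468417) from 100% ± 0 to 43% ± 32. The vesicular transporter gene Slc18b1 fell from 87.3% ± 22.1 to 36.5% ± 11, and the helicase gene Rtel1 fell from 84% ± 15.2 to 39% ± 23.3. The splicing regulator Tra2a fell at a 5′ splice-site choice (chromosome 6, 49245476 to 49245610) from 97.1% ± 2.62 to 81.8% ± 1.31, a change large against its spread.

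Of the other lists, TA had 1 event each in brain targets (Tanc2, a synaptic scaffold, fell from 91.3% ± 15.1 to 52.7% ± 21.6), RNA-binding proteins (Tra2a) and sarcomere genes (Myoz2, a Z-disc protein, 91.7% ± 14.3 in wild type and 66.8% ± 31.3 in 480/480 with overlapping libraries). No gene of the calcium, cytoskeleton, choroid plexus epithelium or other-cell lists had an event. Skipped exons also rose in Lrrc49 from 38% ± 21.3 to 89.6% ± 18.1 and in Xaf1 from 47.4% ± 22.3 to 90.8% ± 15.9. They fell in the non-coding D330041H03Rik from 88.7% ± 19.6 to 43% ± 14.5, Carf from 93.7% ± 11 to 50.3% ± 20.3, Etl4 from 95.2% ± 8.37 to 55.4% ± 22 and the centrosomal gene Cep44 from 100% ± 0 to 63% ± 7.75. Sec22c averaged 95.2% ± 8.31 in wild type and 54.9% ± 43.3 in 480/480 with overlapping libraries. The longer exon form rose in Ddo from 31% ± 17.4 to 100% ± 0 and in Carf from 23.2% ± 1.67 to 85.2% ± 25.6, and intron retention rose in the receptor gene Ntsr2 from 36.4% ± 18.1 to 100% ± 0 and the kinase gene Jak3 from 27.3% ± 11.6 to 85.8% ± 24.5. One mutually exclusive exon of Dolpp1 rose from 24.4% ± 14 to 64% ± 1.16. The TA libraries were the most widely spread, with a median group SD of 10.9 points over skipped exons against 4.92 in 480/480 myotubes, 5.88 in +/480 myotubes and 5.90 in choroid plexus. The groups did not overlap at 58 of 81 events (71.6%, chance 10% before any selection). At 17 events (20.99%) a group was at 0% or 100% in every library.

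In choroid plexus, where 2 libraries of 480/480 were compared with 3 of wild type, Slc4a4, the sodium bicarbonate cotransporter, rose at a 97-base coding exon (chromosome 5, 89232764 to 89232860) from 63.3% ± 16.6 to 100% ± 0 (SD, n = 3 and 2), and the lipoprotein receptor Lrp8 rose from 52.7% ± 11.2 to 92% ± 11.2. Inf2, a formin that remodels actin, rose from 50.9% ± 13.2 to 89.2% ± 5.94, and the polarity kinase Mark2 fell at a coding exon (chromosome 19, 7281798 to 7281959) from 86% ± 3.80 to 60.9% ± 3.61. Opa1, a fusion protein of the inner mitochondrial membrane, rose from 12.2% ± 4.02 to 29.2% ± 4.67, and the transcription factor Nfix fell from 88.9% ± 2.44 to 77.4% ± 2.97.

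By list, 3 of 69 muscle targets had 3 events in choroid plexus, 1 higher (Opa1) and 2 lower (Nfix and Mllt10, 95.7% ± 7.45 to 72.8% ± 18.1). Of brain targets 1 of 42 had an event (Inf2), as did 1 of 103 RNA-binding proteins, the splicing factor Srsf10, which fell from 100% ± 0 to 88.3% ± 6.86. Of cytoskeleton genes 2 had an event (Inf2 and Mark2), of epithelium genes 2 (Lrp8 and Slc4a4, both higher), and of sarcomere, calcium and both other-cell lists none. The largest skipped-exon fall was in the phosphodiesterase gene Pde2a from 76.9% ± 20.2 to 15.7% ± 8.20, and falls followed in Atad3aos from 100% ± 0 to 48.2% ± 19, Gm45844 from 95.2% ± 8.31 to 51.1% ± 9.26, the mRNA export gene Thoc7 from 100% ± 0 to 57% ± 21.9 and Mrvi1 from 100% ± 0 to 58.4% ± 20.4. The non-coding RMST_1 fell from 49.3% ± 15.7 to 6.75% ± 0.778, Appbp2os from 90.4% ± 16.7 to 47.8% ± 3.96, 1300002E11Rik from 82.4% ± 15.7 to 42% ± 2.69 and Xaf1 from 94% ± 10.3 to 54.4% ± 19.4. Zscan22 rose from 48.3% ± 6.99 to 100% ± 0, Ypel1 from 48% ± 28 to 93.6% ± 9.05 and Pgpep1l from 60.3% ± 35.9 to 100% ± 0. Prpf39, a U1-associated splicing factor, fell at a 5′ splice-site choice from 81.9% ± 4.67 to 56.9% ± 5.59, and the longer exon form of Car10 rose from 29.2% ± 9.85 to 100% ± 0. Intron retention rose in the kinetochore gene Cenpt from 18.1% ± 9.43 to 75.3% ± 12.9 and the chromatin gene Hmgn2 from 25.7% ± 21.9 to 79.5% ± 8.20. The groups did not overlap at 92 of 115 events (80%, where chance gives 20% for 3 libraries against 2 before any selection). At 31 events (27.0%) a group was at 0% or 100% in every library. With 2 libraries the SD of the 480/480 group rests on a single difference.

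The 4 tables differed in the kinds of event they hold. Skipped exons were 184 of 243 events (75.7%) in 480/480 myotubes, 69 of 110 (62.7%) in +/480 myotubes, 68 of 115 (59.1%) in choroid plexus and 37 of 81 (45.7%) in TA. Retained introns were 28 of the TA events (34.6%) and 12 of those in 480/480 myotubes (4.94%), while mutually exclusive exons such as those of Tnnt3 and Pdlim3 were 35 (14.4%) in 480/480 myotubes and 3 in TA. Over all tables chi-square was 89.8 (permutation p = 1e-05, the smallest possible). Adjusted p by pairs was 3e-05 for TA against 480/480 myotubes, 3e-05 for choroid plexus against them, 0.00042 for +/480 against 480/480 myotubes and 0.00650 for TA against +/480 myotubes. It was 0.106 for choroid plexus against TA and 0.106 against +/480 myotubes.

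**Figure D3:**
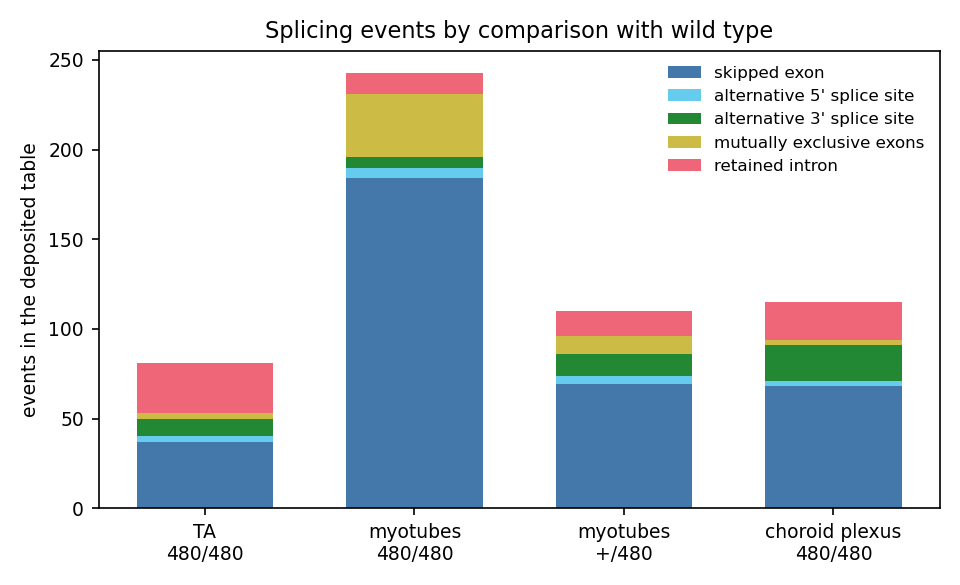
Number of splicing events (vertical axis) in each table, stacked by event type, for TA, myotubes and choroid plexus against wild type of the same tissue. The bars hold 81, 243, 110 and 115 events, and skipped exons are the largest part of each.

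Skipped exons fell more often than they rose in 480/480 myotubes, with 115 of 184 lower (62.5%; exact two-sided binomial p = 0.00172, adjusted over the 4 tables), and in choroid plexus, with 51 of 68 lower (75%; adjusted p = 0.000178). In TA 20 of 37 were lower (54.1%; adjusted exact p = 0.990) and in +/480 myotubes 35 of 69 (50.7%; adjusted p = 1). The share differed between +/480 myotubes and choroid plexus (Fisher's exact test, added after the values were seen, adjusted p = 0.0273). The other 5 pairs had adjusted p of 0.145 or more. These tests treat exons measured in the same libraries as independent (the 184 events lie in 146 genes), so their p-values describe the listed exons and not mice. An exon at 100% in every wild-type library can only fall, for which the binomial test makes no allowance. The median size of a change was 31.6 points in TA, 25.4 in choroid plexus, 22.8 in +/480 myotubes and 21.15 in 480/480 myotubes. TA exceeded 480/480 myotubes by 10.45 points (permutation test of medians, two-sided, adjusted p = 0.00048) and +/480 myotubes by 8.80 (adjusted p = 0.0178, but 0.0556 to 0.262 without the TA wild-type value listed second, the TA 480/480 value listed last, the first or second of myotube wild type or the last of +/480), and the other 4 pairs had adjusted p from 0.0930 to 0.430. These differences were smaller among exons with an SD under 10 points in both groups, where TA exceeded 480/480 myotubes by 0.167 points (adjusted permutation p = 0.963) and +/480 myotubes by 0.483 (adjusted p = 0.963).

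Few exons were shared between tissues. TA and 480/480 myotubes had 4 skipped exons in common, of which both forms of the Josd2 exon fell in each and the exons of Ggta1 and 1700123M08Rik moved in opposite directions. TA and choroid plexus shared 1 (Lrp3), 480/480 myotubes and choroid plexus 2 (Nfix and Inf2), +/480 myotubes and choroid plexus 1 (Tmem134), and all of these had opposite directions. TA and +/480 myotubes shared none, and no exon was in 3 or more tables. Lrp3, a lipoprotein receptor, rose in TA from 57.3% ± 2.12 to 93.8% ± 10.8 and fell in choroid plexus from 98.1% ± 3.35 to 74.8% ± 18.1. The exact binomial p of the shared direction was 1 after adjustment for each pair of tissues, which so few exons cannot move. The number of events tested in each tissue was not used here, so whether this sharing is above or below chance was not tested.

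**Figure D4:**
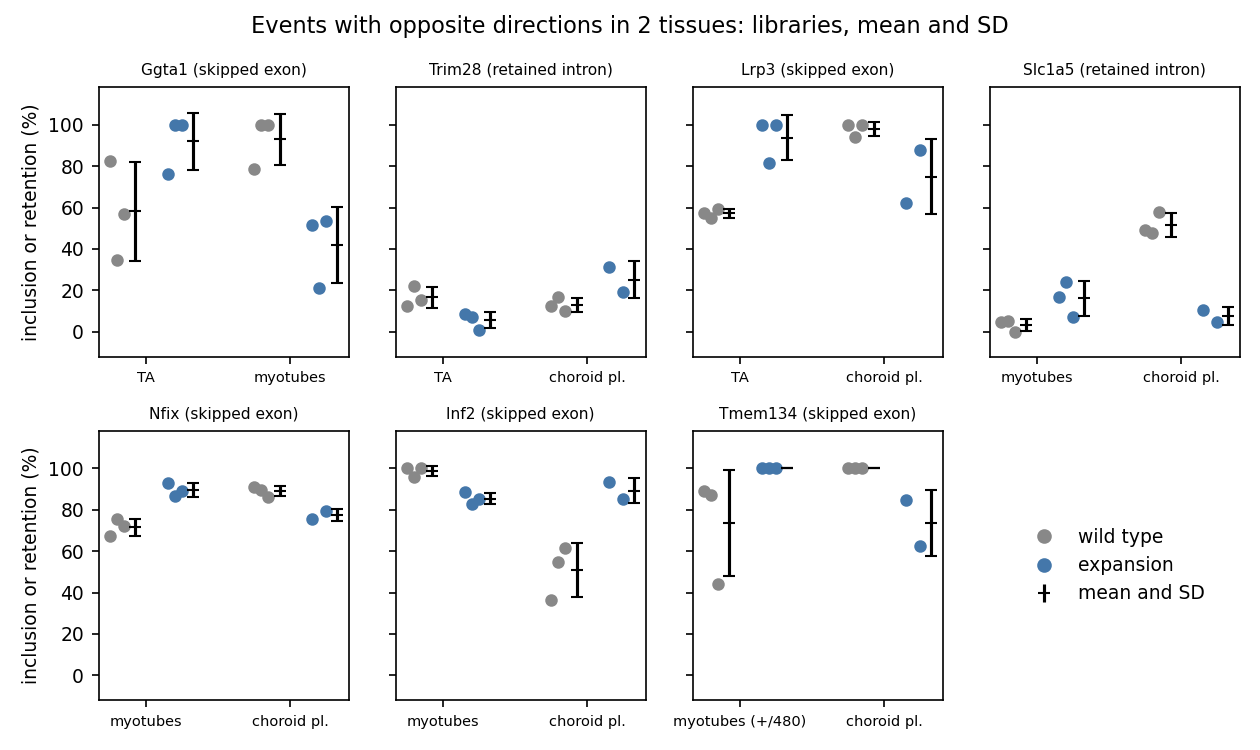
Inclusion (%, vertical axis) of the 7 events found with the same flanking exons or intron in tables of 2 tissues and with opposite directions, in wild type (grey) and expansion (blue) of each tissue; points are libraries, and the bars beside them are mean and SD. Lrp3 rose by 36.5 points in TA and fell by 23.3 in choroid plexus.

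By gene list, muscle targets were 13.0% of the genes with an event in 480/480 myotubes, 9.09% in +/480 myotubes, 2.83% in choroid plexus and 0% in TA. The share in 480/480 myotubes differed from that in TA (Fisher's exact test, two-sided, adjusted p = 0.0206 over 54 tests of lists and pairs) and in choroid plexus (adjusted p = 0.0464). Sarcomere genes such as Ttn, Neb and Tnnt3 were 8.88% in 480/480 myotubes and 0% in choroid plexus (adjusted Fisher's exact p = 0.0206). Cytoskeleton genes such as Clasp1 and Dnm2 were 11.2% in 480/480 myotubes, 0% in TA (adjusted Fisher's exact p = 0.0434) and 1.89% in choroid plexus (adjusted p = 0.0464). A difference in a list between tissues can reflect which of its genes a tissue expresses, sarcomere genes in choroid plexus above all, and expression was not analysed here. The remaining tests, those of the brain, RNA-binding, calcium, epithelium and other-cell lists included, did not pass adjusted p of 0.05. With the authors' FDR at 0.01 or less none of these 5 differences passed, with adjusted p from 0.111 to 0.491. The cytoskeleton difference from TA did not pass without the first or the last value listed for 480/480 myotubes (adjusted Fisher's exact p = 0.0536 each). That from choroid plexus did not pass without either of them (0.0712 each) or without either value for 480/480 choroid plexus (0.114 and 0.0842). The difference of muscle targets from choroid plexus did not pass without the second of those values (0.0842). Over all alternatives the adjusted Fisher p of the 5 differences ran from 0.0158 to 1.

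In 480/480 myotubes many skipped exons had a length divisible by 3. Such a length leaves the reading frame intact when the exon is skipped, as with the Tnnt2, Tnnt3, Cacna1s, Mbnl1 and Rilpl1 exons. Of 178 distinct skipped exons in 480/480 myotubes 125 had such a length (70.2%, 95% Wilson interval 63.1 to 76.5; exact two-sided binomial test against 1 in 3, adjusted p = 5.01e-23). By the same exact test the share was 52.9% in +/480 myotubes (adjusted p = 0.00149), 54.5% in choroid plexus (adjusted p = 0.00112) and 40% in TA (adjusted p = 0.473). Among wholly coding exons it was 83.2% in 480/480 myotubes (109 of 131), 67.4% in +/480 myotubes (31 of 46), 61.5% in choroid plexus (24 of 39) and 60% in TA (9 of 15). The mouse annotation has 56.0% among 9692 coding exons that are skipped in some transcript, and the coding exons of 480/480 myotubes differed from it (exact binomial test, adjusted p = 2.86e-10), while for the coding exons of the other tables p was above the threshold (adjusted exact p = 0.276 in +/480 myotubes, 0.697 in choroid plexus and 0.801 in TA). Over all skipped exons of +/480 myotubes and of choroid plexus, which differed from 1 in 3, the adjusted exact p against the annotated share was 0.806 each. For coding exons 480/480 myotubes differed from choroid plexus (Fisher's exact test, adjusted p = 0.0430), and from TA and +/480 myotubes the adjusted p was 0.0834 each. Among exons with an SD under 10 points in both groups, 77.6% of the coding exons of the other 3 tables (38 of 49) and 86.2% of those of 480/480 myotubes (81 of 94) had such a length (Fisher's exact test, two-sided, p = 0.239). Median length of exons that fell and rose was 84 and 102 bases in 480/480 myotubes, 124 and 95 in +/480 myotubes, 111.5 and 118.5 in choroid plexus and 122 and 120 in TA, with adjusted permutation p of 0.150 or more in each.

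**Figure D5:**
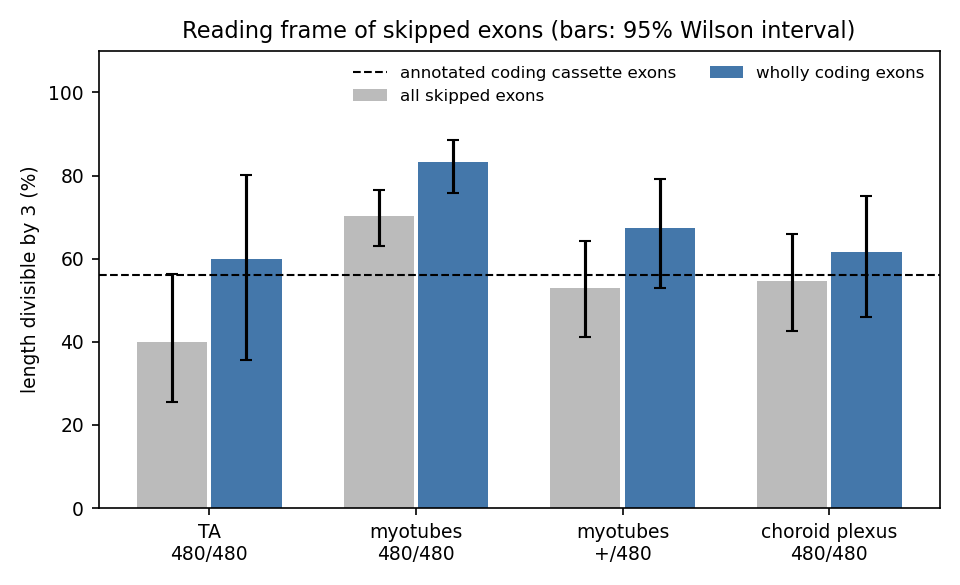
Percentage of skipped exons with a length divisible by 3 (vertical axis) in each table, for all skipped exons (grey) and wholly coding ones (blue), with 95% Wilson intervals as bars; the dashed line is the 56.0% of annotated coding cassette exons. The coding exons of 480/480 myotubes are at 83.2%, with the whole interval above the line.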

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

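Of 11 events found with the same flanking exons, or the same intron, in tables of 2 tissues, 4 moved in the same direction and 7 in opposite directions. A skipped exon of Ggta1 rose in TA from 58.2% ± 24 to 92% ± 13.8 and fell in 480/480 myotubes from 92.9% ± 12.2 to 42% ± 18.2, a difference of 84.8 points. The lipoprotein receptor Lrp3 rose in TA from 57.3% ± 2.12 to 93.8% ± 10.8 and fell in choroid plexus from 98.1% ± 3.35 to 74.8% ± 18.1, a difference of 59.8 points. The transcription factor Nfix rose in 480/480 myotubes from 71.5% ± 4.21 to 89.6% ± 3.23 and fell in choroid plexus from 88.9% ± 2.44 to 77.4% ± 2.97, a difference of 29.5 points. The formin Inf2 fell in 480/480 myotubes from 98.6% ± 2.37 to 85.4% ± 2.77 and rose in choroid plexus from 50.9% ± 13.2 to 89.2% ± 5.94, a difference of -51.6 points. Tmem134 rose in +/480 myotubes from 73.4% ± 25.6 to 100% ± 0 and fell in choroid plexus from 100% ± 0 to 73.7% ± 15.8, a difference of 52.9 points. Retention of an intron of the transcriptional corepressor Trim28 fell in TA from 16.6% ± 5.10 to 5.57% ± 3.91 and rose in choroid plexus from 13.1% ± 3.33 to 25.2% ± 8.84, a difference of -23.2 points. For the amino acid transporter Slc1a5, intron retention rose in 480/480 myotubes from 3.33% ± 2.89 to 16.2% ± 8.58 and fell in choroid plexus from 51.6% ± 5.68 to 7.65% ± 4.17, a difference of 56.8 points. Values are mean and SD over 3 libraries, or 2 in 480/480 choroid plexus.

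The 7 events are listed because every expansion library lay on one side of the wild-type mean in one tissue and on the opposite side in the other. The difference between the tissues was not tested by mouse, because the tissues share mice and the lists of library values do not say which mouse each value is from. A permutation of the genotypes in each tissue apart was run and its p-values are not used, since it treats the tissues as separate animals. The events had also been selected by the authors for a change in each tissue. No explanation of these 7 differences was tested.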

How the results depend on the processing

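The alternatives named in the methods as added were chosen after the data were seen, and the cause of a change was not tested unless fewer events or libraries alone give it. Over the results that answer a comparison, 152 values were unchanged under another setting, 29 no longer passed the threshold, 4 reversed and 32 moved. A test was unchanged if it kept its direction and its side of the threshold, whether or not it had passed. A count was unchanged if it stayed near the main count, and a median if it stayed within the interval of the main median. Counts and medians outside these limits are those that moved. With 1 library left out 321 values were unchanged by these rules, 15 no longer passed, 5 newly passed, 2 reversed and 1 moved. None of 722 leave-one-out values of the 125 named events reversed, and 6 events fell under 10 points. The named events had been selected over all libraries, many for their large changes, so few reversals could arise. The authors' FDR was not recomputed without a library. In all other leave-one-out results, an event was dropped where its change reversed or fell under 10 points. The lower inclusion of skipped exons passed its threshold in every alternative run for 480/480 myotubes (adjusted binomial p up to 0.0316) and choroid plexus (up to 0.0157). No paired analysis was possible because the lists of library values carry no replicate number. Alternatives of the motif search and a minimum of 20 junction reads were not run, for want of a genome sequence and counts. Without counts the effect of depth on any result is unknown.

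With the authors' FDR at 0.01 or less, fewer events were left by construction: 31 (of them 11 skipped exons) in TA, 53 (28) in +/480 myotubes and 47 (25) in choroid plexus. The myotube tables then shared 10 skipped exons and the tissues 1. The change was larger in 480/480 for 80% (exact binomial p = 0.109). Median change in TA was 39.8 points, 18 above +/480 myotubes (adjusted permutation p = 0.0571), and 480/480 minus +/480 myotubes reversed to 1.33. List differences of 480/480 myotubes, with adjusted Fisher's exact p, were 17.4 points for muscle targets against TA (p = 0.327), 17.4 points for muscle targets against choroid plexus (p = 0.111), 11.3 points for sarcomere genes against choroid plexus (p = 0.327), 13 points for cytoskeleton genes against TA (p = 0.491) and 13 points for cytoskeleton genes against choroid plexus (p = 0.317). In choroid plexus 48% of exons had a length divisible by 3 (exact binomial p = 0.184). The median length of lower minus higher exons reversed in TA to -33.5 bases and in choroid plexus to 19.

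With changes of 20 points or more, 130 events (101 skipped exons) were left in 480/480 myotubes, 45 skipped exons in +/480 myotubes and 72 events (42) in choroid plexus. By construction the medians moved, to 28.4, 29.5 and 33.8 points. TA exceeded 480/480 myotubes by 6.68 points (adjusted permutation p = 0.0512) and +/480 myotubes by 5.58 (0.363). The myotube tables shared 14 exons, 78.6% of them larger in 480/480 (exact binomial p = 0.0574), and the tissues 5. Lower inclusion in +/480 myotubes turned to 46.7%, and the share of lengths divisible by 3 there was 42.2% (exact binomial p = 0.250). List differences, with adjusted Fisher's exact p, were 14.2 points for muscle targets against TA (p = 0.146), 12.7 points for muscle targets against choroid plexus (p = 0.148), 7.55 points for sarcomere genes against choroid plexus (p = 0.419), 6.60 points for cytoskeleton genes against TA (p = 0.744) and 3.66 points for cytoskeleton genes against choroid plexus (p = 1.00). The length difference in TA reversed to -0.500 bases. Counting the same gene with any event type, 18 genes were shared between tissues.

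Without events that have a group at 0% or 100% in every library, TA exceeded +/480 myotubes by 6.95 points (adjusted permutation p = 0.118), and list differences, with adjusted Fisher's exact p, were 10.8 points for muscle targets against choroid plexus (p = 0.122), 10 points for sarcomere genes against choroid plexus (p = 0.0738), 12 points for cytoskeleton genes against TA (p = 0.0738) and 9.40 points for cytoskeleton genes against choroid plexus (p = 0.182). With an SD under 10 points in both groups, 21 events (9 skipped exons) were left in TA, 48 (32) in +/480 myotubes and 55 (36) in choroid plexus. Median changes were 18.2, 18, 17.7 and 18.9 points in TA, 480/480 myotubes, +/480 myotubes and choroid plexus. TA minus 480/480 myotubes was 0.167, TA minus +/480 myotubes 0.483, TA minus choroid plexus -0.650 (reversed) and 480/480 minus +/480 myotubes 0.317 (reversed), with adjusted permutation p = 0.963 each. The myotube tables shared 17 exons and the tissues 1. List differences, with adjusted Fisher's exact p, were 17.3 points for muscle targets against TA (p = 0.567), 13.3 points for muscle targets against choroid plexus (p = 0.248), 12.7 points for sarcomere genes against choroid plexus (p = 0.148), 13.6 points for cytoskeleton genes against TA (p = 0.808) and 11.6 points for cytoskeleton genes against choroid plexus (p = 0.248). Length differences reversed to -136 bases in TA and 6 in choroid plexus.

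With 1 library left out, median change in choroid plexus ran from 24.1 to 33.0 points, the highest without the second 480/480 value. TA minus choroid plexus ran from -1.43 to 7.90 points (reversed without that value, and 7.50 with adjusted permutation p = 0.0473 without the last wild-type value). For 480/480 myotubes minus choroid plexus the range was -11.9 to -2.95, newly past the threshold without the first wild-type value (-5.30) or either 480/480 value (-5.28 and -11.9) of choroid plexus. For +/480 myotubes minus choroid plexus it was -10.2 to -1.25, newly past it without the second 480/480 value. TA minus +/480 myotubes ran from 5.17 to 10.5. It no longer passed without the second TA wild-type value (5.17), the last TA 480/480 value (7.48), the first or second myotube wild-type value (8.82 and 8.11) or the last +/480 value (7.46). Muscle targets against choroid plexus ran from 9.89 to 10.8 points, failing without the second choroid plexus 480/480 value. Cytoskeleton genes against choroid plexus ran from 8.48 to 9.63, failing without either choroid plexus 480/480 value (9.02 and 9.16) or the first or last 480/480 myotube value (8.48 each). Against TA they ran from 10.4 to 11.5, failing without the first or last 480/480 myotube value (10.4 each). Lower exons in +/480 myotubes ran from 48.5% to 52.2%, reversed without the first wild-type value. The share larger in 480/480 ran from 65.6% to 87.5%, failing without the second +/480 value (65.6%) or the first 480/480 value (68.8%). The mean difference ran from 4.10 to 6.82 points, failing without the first +/480 value (4.10). The median length of lower minus higher exons in CP 480/480, bases, ran from -10 to 4.5, reversed without the first 480/480 value of choroid plexus.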

Other observations

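The genes of this and the next paragraph, and all tests of this part, were chosen after the results were seen. The genes are single examples, and no gene group was tested with them. Dnm1l, which drives mitochondrial fission, included its 78-base coding exon more in 480/480 myotubes (from 36.8% ± 9.12 to 66.7% ± 12.3, SD, n = 3 each) and also a 33-base exon (from 14.2% ± 1.76 to 33.9% ± 8.64). Mfn2, which fuses outer membranes, fell at a 5′ UTR exon from 89.6% ± 5.08 to 74.4% ± 1.36, and Opa1 rose in choroid plexus from 12.2% ± 4.02 to 29.2% ± 4.67 (n = 3 and 2). Aak1, a kinase of clathrin-mediated endocytosis, had 4 coding exons at 100% in every wild-type myotube library and at 71.9% ± 4.78, 76.9% ± 1.79, 79% ± 4.86 and 80.2% ± 1.80 in 480/480. Numb, a substrate of that kinase and an endocytic adaptor, fell in choroid plexus from 33.9% ± 4.29 to 16.4% ± 5.02.

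In choroid plexus, a coding exon of the cilia gene Cfap54 fell from 94.7% ± 3.18 to 84.4% ± 6.79 (SD, n = 3 and 2). Coding exons of the cilia genes Cfap99 and Lrrc6 fell from 97.6% ± 4.10 to 75.2% ± 22.6 and from 100% ± 0 to 85.5% ± 0.919. Cep170 of the centrosome fell from 100% ± 0 to 71.4% ± 8.49. A 110-base exon of the splicing factor Prpf39 fell from 72% ± 5.67 to 33.5% ± 2.26, and a 5′ UTR exon of the RNA-binding Hnrnpf fell from 100% ± 0 to 78.5% ± 5.66. In myotubes the imprinted non-coding Meg3 rose at an exon on chromosome 12 from 6.07% ± 10.5 to 30.9% ± 7.69 in 480/480, and its neighbour Rian rose in +/480 from 23.3% ± 20.2 to 94.6% ± 9.30. Sympk, a neighbour of Dmpk on chromosome 7, fell at a 5′ UTR exon from 37.4% ± 8.50 to 12.2% ± 1.44 in 480/480 and to 17.5% ± 5.11 in +/480 (n = 3 each).

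Choroid plexus had more event genes on chromosome 7, which carries Dmpk, than the other tables: 18 of 106 (16.98%, 95% Wilson interval 11.02 to 25.3), against 8.80% of 18703 annotated multi-exon protein-coding genes (exact two-sided binomial p = 0.0230, adjusted over 4 tables). The share was 10.1% in TA, 8.88% in 480/480 and 9.09% in +/480 myotubes (adjusted exact p = 0.892 each). Chance placement gave a chromosome with as large a difference in few permutations (p = 0.0122 over 20 chromosomes). The pattern was found in these same genes, and the permutation p is not corrected for the choice among 4 tables. Neither it nor the binomial p can therefore exclude chance. The event genes were also not limited to protein-coding ones, unlike the annotated set. The pattern was noticed while reading the tables, with windows around Dmpk looked at first and the whole chromosome kept. Within 10, 20 and 30 Mb of Dmpk lay 6, 11 and 14 of the 106 choroid plexus genes (5.66%, 10.4% and 13.2%), against 2.15%, 3.48% and 4.51% of annotated protein-coding genes (unadjusted exact binomial p = 0.0276, 0.00121 and 0.000302, and 0.0111 for the whole chromosome). The shares were 4.35%, 5.80% and 7.25% in TA, 2.96%, 3.55% and 5.92% in 480/480 myotubes and 1.14%, 3.41% and 4.55% in +/480 myotubes (unadjusted exact binomial p of 0.186 or more each). These windows are what drew attention to the pattern, so they are no test of it. TA and 480/480 myotubes, from the same mice and with the same linked sequence, together had 20 of 233 event genes on chromosome 7 (8.58%, Wilson interval up to 12.9; exact binomial p = 1 against the annotated share), so no excess was seen in genes with events in those tissues. Some of the choroid plexus genes on chromosome 7 also had events in those tissues, Trim28 and Lrp3 in TA and Slc1a5 and Zfp939 in 480/480 myotubes. The events of Trim28, Lrp3 and Slc1a5 moved in the opposite direction there, while Zfp939 rose in both tissues. The 18 chromosome 7 genes had a median distance of 11.6 Mb from Dmpk, against 29.4 Mb for the 1646 annotated multi-exon genes of that chromosome, a difference within the range of random draws (permutation p = 0.391), which does not decide for or against linked sequence in these genes. The pattern may come from linked sequence, may be biological or may be chance, and these were not told apart.

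The larger in-frame share of coding exons in 480/480 myotubes may come in part from the spread between libraries. Coding exons of the other 3 tables with an SD under 10 points in both groups were in frame in 77.6% (38 of 49), above the rest of those tables at 51.0% (26 of 51, Fisher's exact p = 0.00697), and against 86.2% of such exons in 480/480 myotubes the difference had p = 0.239. Several exons of one gene do not account for it, since with 1 coding exon per gene the share was 83.8% of 105 exons, against 63.4% of 93 in the other tables (Fisher's exact p = 0.00118). Between tissues, the coding exons of 480/480 myotubes differed from choroid plexus (adjusted Fisher's exact p = 0.0430), with p = 0.0834 against TA and also against +/480 myotubes, the same tissue. No biological cause of the difference was tested.

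The larger changes in 480/480 than in +/480 myotubes were kept where the spread is small. With an SD under 10 points in both groups, 17 exons were shared and 14 of them (82.4%) had the larger change in 480/480 (exact two-sided binomial p = 0.0127), with a mean difference of 6.75 points (sign-flip permutation p = 0.00037), which argues against a wider spread as the whole cause. Over the 31 pairs of events with the same exon and flanks, at 30 exons, the SD was larger in 480/480 for 16 (exact binomial p = 1), with medians of 6.29 and 5.11 points. A test of the 10-point threshold among exons with 20 points or more in +/480 was dropped, since choosing exons by that value favours a larger change in +/480, and an effect of that threshold stays open. The p-values of this paragraph, too, describe exons measured in the same libraries and not mice. A dose of the expanded allele may be the cause, and remains a hypothesis.

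Another pattern, that few exons were shared between tissues, was tested and then set aside for the chromosome 7 pattern. Of 42 TA and choroid plexus exons with an SD under 10 points in both groups 0 moved in the same direction in another tissue, against 2 of the other 59 (Fisher's exact p = 0.509), which decides nothing.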
